A study of Caenorhabditis elegans with 2 samples.

How the data were processed

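DPFF-1 tagged with GFP was precipitated with an anti-GFP antibody from sonicated chromatin of whole young adult worms in 2 biological replicates, numbered 3 and 4 in the labels, which together form the only group. The labels call them biological replicates. The antibody field of the labels names dpff-1 while their description states an anti-GFP antibody, and the description was followed here. No further replicates, input reads or expression data were analysed here. Because peaks were the only values, no mean and SD between replicates was formed; the replicates were compared through their ranked lists.

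The authors deposited, for each replicate and for both replicates together, a list of 30000 peaks and background regions made as input for the irreproducible discovery rate (IDR) procedure, and the optimal set of peaks that the IDR threshold kept from the pooled list, each in the ce10 and the ce11 build, per the labels and the deposited file listings. Per the deposited listings, each list was called on the ChIP alignments against a control alignment, so the values are relative to a control. The aligner, the peak caller, their versions and the IDR threshold were not given in the sources used here. The signal value of a peak is the authors' measure of enrichment over the control, on a scale that the deposited files do not name and that differs between the pooled and the single-replicate lists, so signal was used only to rank and describe peaks within a list. The authors also deposited a −log10 q-value for each peak, and a p-value was not given (the field holds a placeholder). The summit offset is the deposited distance of the summit from the start of the peak; nearly all peaks have a fixed width with the summit in the middle. The optimal set in ce11 is made up of the 422 regions of highest signal in the pooled list, and that in ce10 of the 419 highest.

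The ce11 lists were analysed with the WBcel235 genome sequence and the Ensembl release 115 annotation, which are of the same build (19973 protein-coding genes on the 6 nuclear chromosomes). The names and amino acids of tRNA genes were taken from the RefSeq annotation of the same assembly by gene identifier. The ce10 lists were used only to repeat counts and overlaps, and no coordinates were converted. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9, with a fixed random seed of 1. For the rank and the signal of an optimal peak in a replicate, the overlapping region of highest signal was taken, a choice made after the values had first been seen.

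The tests, gene lists and alternatives were fixed before the data were examined. Overlap between replicates was the share of the 422 top regions of replicate 3 that overlapped at least 1 bp of a top region of replicate 4, compared with 1000 random circular shifts within chromosomes (100 for the top 5000 and 20 for the whole lists). The share of summits within 500 bp of a protein-coding gene start, the feature class of each summit (the first match of promoter, 5′ UTR, CDS, 3′ UTR, non-coding gene, intron and intergenic, with the promoter class reaching 500 bp upstream) and the number of summits within 250 bp of each of 9 classes of non-coding gene were compared with shifts of the same kind, two-sided. The smallest p these shifts can give is 0.002 two-sided and 0.001 one-sided. Counts per chromosome were compared with chromosome length by exact binomial tests. The 23 gene lists, defined by gene symbol, were tested with two-sided Fisher's exact tests against all other protein-coding genes; they were ribosomal proteins, translation factors, respiratory chain and ATP synthase, proteasome, chaperones, core histones, splicing, cell cycle and DNA replication, SWI/SNF subunits, other chromatin regulators, germline and early embryo, major sperm proteins, muscle, intestine, collagens, pan-neuronal, neuropeptides and insulins, homeobox, nuclear hormone receptors, chemoreceptors, F-box and MATH/BATH, C-type lectins and detoxification enzymes. Signal at and away from promoters was compared by a permutation test of medians, and GC content by a sign-flip permutation test, each with 100000 resamples. Presence of 6-mers within 50 bp of the summit was compared with the flank centred 500 bp to the right by exact McNemar tests. Families of tests were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Summits close to each other are not independent, which the shifts keep and the binomial and Fisher tests do not.

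Genes were named by a rule set in advance: the protein-coding genes with a start within 500 bp of the summits of the 25 peaks of highest signal, or else the position and feature class of the peak; up to 3 members of highest signal from each gene list with an adjusted p under 0.05; every SWI/SNF subunit gene with a peak, dpff-1 and unc-119; and up to 2 genes of highest signal from each class of non-coding gene with an adjusted p under 0.05. Other names were added after the values were seen, as were the non-coding genes at the 25 peaks.

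The tests were tested on simulated data. Uniformly placed summits were called different from shifts for the promoter share in 4% of 100 simulated sets, and 140 of 150 planted promoter summits were recovered as an excess. Random sets of genes gave 0.12 gene lists called per set over 100 sets. With planted members, all 21 lists of 30 or more genes were recovered. The planted share was above that seen in any real list, so this does not cover effects of the size observed. For 6-mers, uniform summits gave 0 calls, and a planted word ranked 1. All 200 shared peaks planted in the overlap test were found.

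The depth of sequencing is unknown, as the lists carry no read counts, so precision was given as Wilson 95% intervals of counts of peaks, which cover counting error only. Alternatives were a stricter set (the 211 optimal peaks of higher signal), the top pooled peaks without IDR, the top peaks of either replicate alone, other windows (250 and 1000 bp for gene starts, 100 and 500 bp for non-coding genes, 10 and 40 kb for the transgene loci), other definitions of overlap (50% reciprocal, or summits within 100 bp), transcript starts, the nearest start only, merging of peaks within 5 kb, gene numbers in place of length, and the ce10 build. The top pooled peaks without IDR are the optimal set itself, so that alternative could change nothing. Leaving out summits near tRNA, snRNA and snoRNA genes, the alternatives for chromosome III and those for a sequence word on X were added after seeing the data, as was the comparison of signal near and away from short RNA genes. No paired analysis was possible because there is only 1 group.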

Results

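Binding of DPFF-1 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole young adult Caenorhabditis elegans, collected 48 h after starved L1 larvae were released from synchronization. DPFF-1 is the worm member of the d4 family of PHD finger proteins, whose mammalian relatives are subunits of SWI/SNF (BAF) chromatin remodelling complexes. The worms carried an integrated dpff-1 transgene whose product ends in a GFP tag, in a strain with an unc-119 mutation, and an antibody against GFP was used for the precipitation. The 2 samples form 1 group of 2 biological replicates, numbered 3 and 4 in the labels, so the comparisons are between the replicates and between peaks and the genome. No other condition was given, and the control reads were not analysed here. Read depth is unknown, since the peak lists hold no read counts. Each replicate list and the list from both replicates together (the pooled list) holds 30000 ranked regions, of which the authors kept 422 in the ce11 build as the optimal set after an irreproducible discovery rate (IDR) threshold. All positions are in ce11, and the signal values are the authors' own, used only within a list.

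The highest DPFF-1 signal fell at a mixture of protein-coding promoters, short RNA genes and sites with neither. Of the 25 peaks with the highest signal, 7 had a summit within 500 bp of a protein-coding gene start, 11 others lay within 250 bp of a non-coding gene, and 7 had neither. The 7 protein-coding genes were rpl-3, ufbp-1, kin-14, kel-3, tasp-1, ego-1 and R107.5. The peak at rpl-3 (WBGene00004414), which encodes a protein of the large ribosomal subunit, ranked 2 of 422 with a signal of 295.0 (chromosome III, 3867443 to 3867669), and its summit lay 309 bp upstream of the annotated start. The peak upstream of ufbp-1 (WBGene00022865) ranked 9 with a signal of 220.3. The kin-14 peak (WBGene00002198, a kinase gene) ranked 10 with a signal of 215.5 and had its summit in the 5′ UTR, 130 bp inside the gene. The kel-3 peak (WBGene00002185) ranked 11 with a signal of 215.0, and its summit also fell within the annotated body of ant-1.1. The tasp-1 peak (WBGene00010480, a threonine aspartase family gene) ranked 12 with a signal of 208.5 and a summit 33 bp from the start. The peak at ego-1 (WBGene00001214), which encodes a germline RNA-directed RNA polymerase, ranked 17 with a signal of 203.9. The R107.5 peak (WBGene00011300) ranked 25 with a signal of 185.5.

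The peak of rank 1 lay on chromosome III from 835799 to 836153 with a signal of 306.6, and its summit was in coding sequence of dos-3, 3006 bp from the nearest protein-coding start. The peak of rank 4 (chromosome II, 5661637 to 5661983; signal 275.9) was in an intron of mdt-26, and that of rank 6 (chromosome X, 6296315 to 6296770; signal 237.0) in an intron of mom-1. The peaks of rank 16 (chromosome I, 12654585 to 12655040), rank 18 (chromosome X, 11094005 to 11094460), rank 20 (chromosome III, 4195324 to 4195779) and rank 21 (chromosome X, 4209028 to 4209483) were intergenic, with signals from 190.9 to 205.3. Among the 11 with a non-coding gene, rank 3 (chromosome I, 4172305 to 4172478; signal 284.7) was intergenic beside sls-2.4, and rank 14 (chromosome II, 5543648 to 5544103; signal 206.5) was intergenic beside sls-2.2. Both genes encode spliced leader 2 (SL2) RNA, the leader trans-spliced onto downstream genes of operons. Rank 5 (chromosome I, 13463748 to 13464203; signal 253.3) fell in rpr-1, the RNA of ribonuclease P, which lies within ints-8. Rank 8 (chromosome V, 12303410 to 12303865; signal 234.1), rank 22 (chromosome V, 8500314 to 8500769; signal 189.6) and rank 24 (chromosome I, 2514114 to 2514569; signal 187.5) were at the snoRNA genes C51F7.4, ZK994.7 (in an intron of pxn-1) and Y23H5B.10. Rank 19 (chromosome X, 8036234 to 8036689; signal 198.9) was intergenic beside the arginine tRNA gene C18A11.t2, and rank 23 (chromosome II, 12944508 to 12944963; signal 188.5) had its summit in coding sequence of F58G1.7 beside the snRNA gene sup-6. Ranks 7, 13 and 15 fell in the non-coding genes F16A11.7 (chromosome I, 9382931 to 9383386; signal 234.3), F52D10.7 (chromosome X, 11605742 to 11606197; signal 207.5) and linc-128 (chromosome V, 1151264 to 1151719; signal 206.4).

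The optimal set held 422 peaks with signals from 89.3 to 306.6 (median 108.0) and a −log10 q between 1.61 and 2.26, as the authors gave them. Of these, 175 had a q of 0.01 or lower and all 422 a q of 0.05 or lower. The usual width was 456 bp, found in 410 of the 422, so widths do not measure the extent of binding. Some of the 422 peaks overlapped each other, and merging these left 409. The corresponding set in ce10 held 419 peaks. Counted singly, replicate 4 had 427 regions with a q of 0.01 or lower and replicate 3 had 0, while 1465 and 890 regions had a q of 0.05 or lower.

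The replicates shared far more regions than chance placement gave. All 25 peaks of highest signal were among the 422 top regions of both replicates, and 24 of the 25 ranked within the first 100 of each; R107.5 was the exception, ranking 252 in replicate 3 and 9 in replicate 4. Of the first 100 optimal peaks, 53 ranked within the first 100 of both replicates. High ranks of these peaks are largely built in, since they were picked on the pooled signal of the same replicates. The rpl-3 peak ranked 2 and 4, the sls-2.4 peak 5 and 1, and the dos-3 peak 1 and 3 in replicates 3 and 4. Of the 422 top regions of replicate 3, 196 (46.4%, Wilson 95% interval 41.7 to 51.2) overlapped a top region of replicate 4 by at least 1 bp. Random circular shifts of replicate 4 within chromosomes gave a mean of 0.392% and at most 1.90% over 1000 shifts (one-sided permutation p = 0.001, the smallest these shifts can give). The shared percentage was 55% for the top 100, 42.6% for the top 1000, 36.8% for the top 5000 and 51.6% for the whole lists, where shifts alone gave 24.2%. Across 421 optimal peaks overlapped by both replicate lists, the signals had a Spearman rho of 0.199 and a Pearson r of 0.319 on the log2 scale, and across all 15484 overlapping regions of the whole lists 0.262 and 0.379. These correlations are across peaks, which are not independent replicates, and selection of the optimal peaks on their pooled signal can itself lower the correlation.

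**Figure D1:**
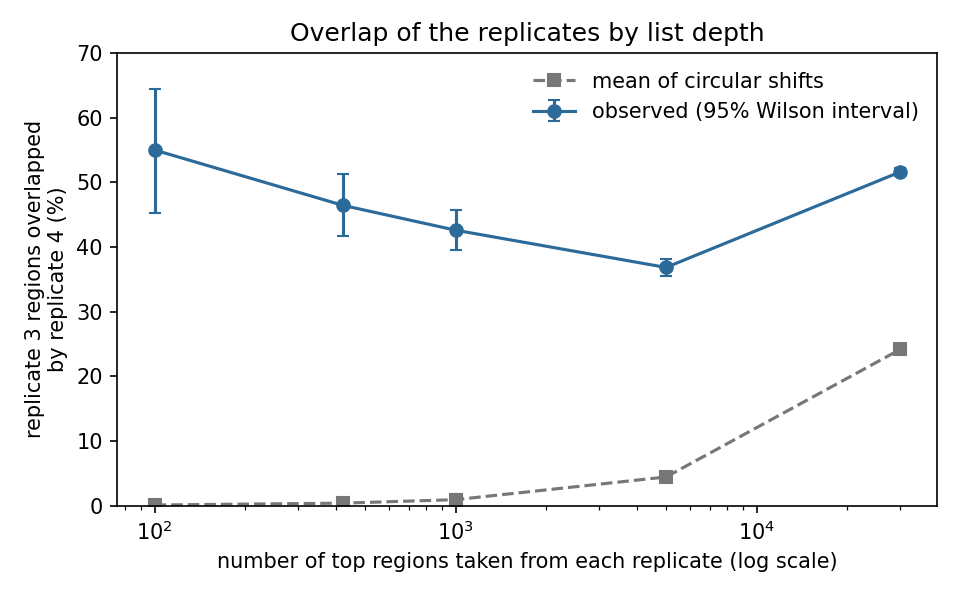
Percentage of the top regions of replicate 3 that overlap a top region of replicate 4 by at least 1 bp, against the number of regions taken from each list (log scale), with 95% Wilson intervals; squares give the mean of circular shifts. The observed share was 55% for the top 100 and 46.4% for the top 422, where the shifts gave 0.105% and 0.392%.

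**Figure D2:**
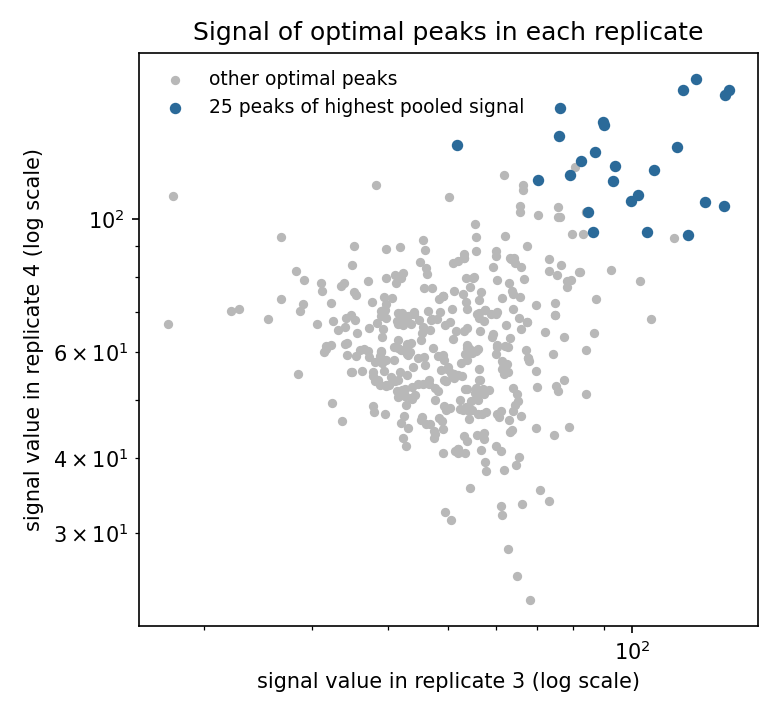
Signal value of each optimal peak in replicate 3 (horizontal, log scale) and in replicate 4 (vertical, log scale), taken from the highest overlapping region of each list; blue points are the 25 peaks of highest pooled signal. The blue points lie towards the upper right, and the grey points form a cloud with a Spearman rho, over all 421 points, of 0.199.

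Each replicate was also set against the optimal set, which was made from the same reads, so overlap is built in and was not tested against chance. The 422 top regions of replicate 3 overlapped 281 optimal peaks (66.6%, Wilson 95% interval 62.0 to 70.9) and those of replicate 4 overlapped 308 (73.0%, 68.6 to 77.0). Both did so for 195 peaks (46.2%), exactly 1 of them for 199 (47.2%) and neither for 28 (6.64%). In the whole lists, replicate 3 overlapped 421 and replicate 4 all 422. Intervals cover counting error only.

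DPFF-1 summits lay near protein-coding gene starts more often than shifted summits did, and less often in introns. Of the 422 summits, 146 (34.6%, Wilson 95% interval 30.2 to 39.3) were within 500 bp of the start of a protein-coding gene, against a mean of 18.6% and a central 95% of 14.9 to 22.3 under circular shifts (two-sided permutation p = 0.002, the smallest these shifts can give). When each summit was given a single class, the 500 bp upstream of a start held 84 summits (19.9%, against 9.29% under shifts), 5′ UTRs held 16 (3.79%, against 1.66%) and non-coding genes held 48 (11.4%, against 4.28%). Introns held 62 (14.7%, against 32.9%). These 4 classes passed the permutation test after Benjamini-Hochberg adjustment over 7 classes, with an adjusted p of 0.00699 for 5′ UTRs and 0.00466 for the other 3. Coding sequence with 85 summits (20.1%, against 23.8%; adjusted permutation p = 0.0932), 3′ UTRs with 19 (4.50%, against 2.80%; adjusted permutation p = 0.0932) and intergenic sequence with 108 (25.6%, against 25.3%; adjusted permutation p = 0.921) did not differ from shifts by this test. Signal did not differ between peaks near starts and the others by the test used: the median was 106.4 for the 146 and 109.1 for the other 276, a difference of -0.04 on the log2 scale (two-sided permutation test, p = 0.355).

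**Figure D3:**
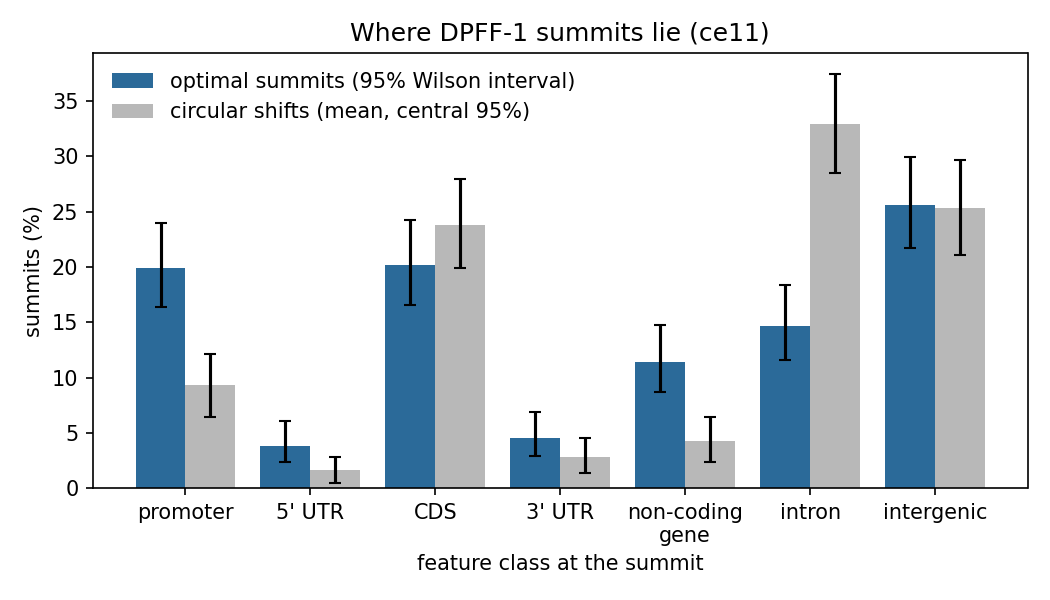
Percentage of the 422 optimal summits in each feature class (blue, with 95% Wilson intervals) and the mean of 1000 circular shifts (grey, with their central 95%). Promoters hold 19.9% of summits against 9.29% under shifts, and introns 14.7% against 32.9%.

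Of 19973 protein-coding genes, 151 (0.756%) had a start within 500 bp of a summit, and among 23 gene lists the ribosomal protein genes were enriched and the chemoreceptor genes depleted. Among ribosomal protein genes, 6 of 81 (7.41%) had a peak, against 0.729% of other genes, an odds ratio of 10.9 (95% interval 3.81 to 25.4; two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.000791). The members with the highest signal were rpl-3, rpl-20 (WBGene00004432; signal 133.5, rank 86, chromosome IV) and rps-26 (WBGene00004495; signal 127.5, chromosome I); the others were rpl-35, rpl-15 and rpl-41.2. All 6 summits lay 283 to 418 bp upstream of the annotated start, so that no ribosomal protein gene had a summit within 250 bp and the enrichment was not seen with that window (0 of 81). The rpl-20 summit, 283 bp from that start, was nearer to the start of Y17G9B.5 (179 bp). The rps-26 summit, 418 bp from that start, was nearer to the start of tmem-107 (39 bp) and to the snoRNA gene F39B2.14 (100 bp). Among chemoreceptor genes of the G protein-coupled families, used in chemosensory neurons, 1 of 1309 had a peak (0.0764%, against 0.804%; odds ratio 0.0944, 95% interval 0.00237 to 0.535; Fisher's exact test, adjusted p = 0.00859). That gene was srh-269 (WBGene00005475; signal 90.9, rank 398), and its summit was also near the glutamine tRNA gene T03E6.t1. With the 211 peaks of higher signal alone, or a window of 250 bp, no chemoreceptor gene had a peak and the adjusted exact p rose to 0.116 and 0.104.

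The remaining 21 lists did not pass the adjusted test. Chaperones came closest, with 3 of 60 genes (5.00%; odds ratio 7.03, 95% interval 1.39 to 21.99; Fisher's exact test, adjusted p = 0.0811). These were hsp-1 (signal 166.2, rank 41), which encodes a constitutive HSP70, the chaperonin gene cct-8 (signal 130.8) and dnj-13 (signal 113.3). The cct-8 summit lay 476 bp from its start and nearer, at 145 bp, to that of Y55F3AR.2. Because the list was made by gene symbol, a chaperone gene that carries only a sequence name would be missing from it. F44E5.4 and F44E5.5, both at the peak of rank 32 (signal 175.1), carry only sequence names and were in no list. What their products are was not checked here, so the count of 3 chaperone genes may be too low. Of the SWI/SNF subunit genes, to whose complex the mammalian relatives of DPFF-1 belong, 0 of 13 had a peak, and the interval of the odds ratio reached 43.5, so an enrichment was not excluded. Cell cycle and replication genes had 2 of 49 (pcn-1 and cdc-48.1), other chromatin regulators 2 of 62 (set-16 and spr-2) and germline and early embryo genes 2 of 67. Translation factors, respiratory chain, splicing, intestine, nuclear hormone receptor and detoxification genes each had 1. The 11 lists without a peak held 1312 members and included core histones, proteasome, muscle, collagen, pan-neuronal, neuropeptide and homeobox genes.

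Short RNA genes carried the clearest enrichment. Within 250 bp of a gene body lay 36 summits for snoRNA genes (mean under shifts 0.856) and 33 for tRNA genes (1.30). For snRNA genes there were 20 (0.324) and for miRNA genes 5 (0.545). Each of these passed the two-sided permutation test (adjusted p = 0.00257, from the smallest p the shifts can give). For miRNA genes the call was lost without replicate 3, where the excess over the shifts fell from 4.46 to 2.44 (permutation test, adjusted p = 0.0617). In all, 88 of the 422 summits (20.9%) were near a tRNA, snRNA or snoRNA gene, and only 16 of the 88 were also near a protein-coding start. These 88 peaks had a higher median signal than the other 334, 115.03 against 106.45, a difference of 0.11 on the log2 scale (two-sided permutation test, p = 0.00671, a test chosen after seeing the data). The genes of highest signal in each class were sls-2.4 and sls-2.2 for snRNA (ranks 3 and 14), C51F7.4 and C51F7.3 for snoRNA (both at the peak of rank 8), C18A11.t2 (arginine) and F41D9.t3 (asparagine) for tRNA (ranks 19 and 42), and mir-52 and mir-51 for miRNA (ranks 40 and 58). The summit at C18A11.t2 lay 223 bp from that gene. The tRNA peaks included F41D9.t3 on chromosome X from 8404499 to 8404571, with the summit inside the gene and a signal of 165.3. The mir-52 precursor (chromosome IV, 14034008 to 14034107) held the summit of its peak, with a signal of 167.6.

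The class of other ncRNA genes had 92 summits against 17.01 under shifts (adjusted permutation p = 0.00257). It was led by rpr-1 and by R12E2.18, which overlaps sls-2.4 on the other strand and shares its peak. Of the 92, 52 were also near a tRNA, snRNA, snoRNA or miRNA gene, and the other 40 still exceeded the 15.9 that shifts gave for such places (permutation p = 0.002, the smallest these shifts can give). Fewer summits than under shifts lay near piRNA genes (4, against 15.1) and pseudogenes (2, against 16.6), each with an adjusted permutation p of 0.00257. The piRNA genes of highest signal were 21ur-14704, at the same peak as the snRNA gene sup-39, and 21ur-14659; the pseudogenes were D1046.t1, at the same peak as the snoRNA gene D1046.6, and wago-2. Near lincRNA genes there were 3 summits (1.48 under shifts, adjusted permutation p = 0.436), so that class did not differ by this test. Near rRNA genes there were 0 summits (0.070 under shifts). With so low an expectation the test could not show a depletion there.

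**Figure D4:**
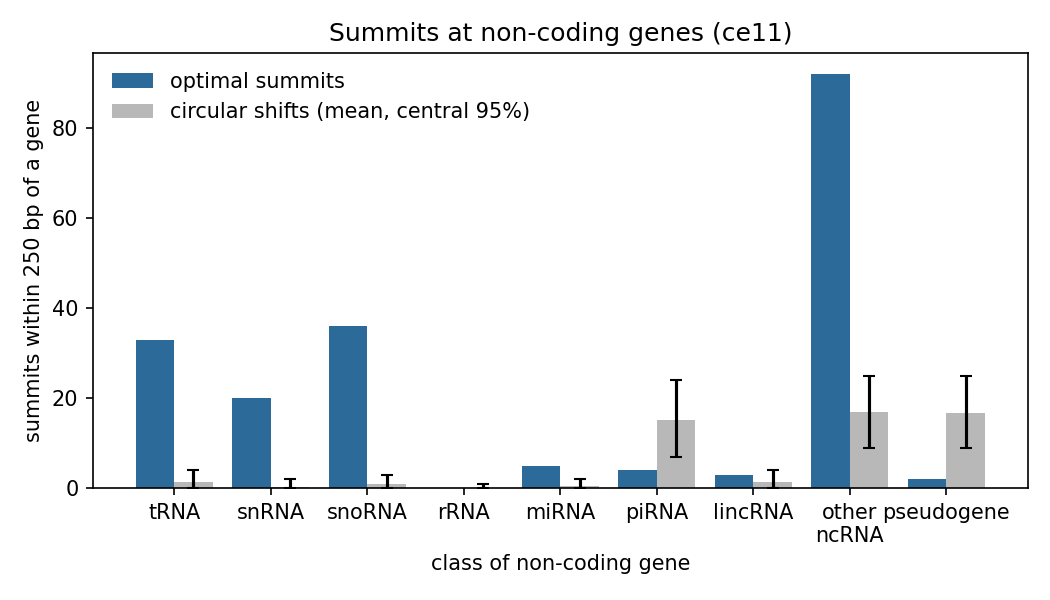
Number of optimal summits within 250 bp of a gene of each non-coding class (blue) and the mean of 1000 circular shifts (grey, with their central 95%). The tRNA, snRNA and snoRNA bars stand at 33, 20 and 36 against 1.30, 0.324 and 0.856 under shifts, and piRNA genes and pseudogenes lie below the shifts.

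Chromosome III carried more peaks than its length gives and chromosome V fewer. Chromosome III had 91 of the 422 peaks (21.6%, Wilson 95% interval 17.9 to 25.7) against 13.7% of the nuclear genome (two-sided exact binomial test, Benjamini-Hochberg adjusted p = 8.4e-05). Chromosome V had 68 (16.1%, 12.9 to 19.9) against 20.9% (exact binomial test, adjusted p = 0.0492). Chromosome X had 61 (14.5%, 11.4 to 18.1) against 17.7%, which did not pass the threshold (exact binomial test, adjusted p = 0.170). Most of the tRNA genes with a summit were on X, where no snRNA or snoRNA gene had one. How many of all 612 tRNA genes lie on X was not counted, so a preference for those on X was not tested. X was not counted again without the summits at tRNA genes, so a shortage of other peaks on X was not tested. The X result depended on the setting: the ratio to expectation was 0.818 by length, 0.711 in the top regions of replicate 4 alone, where it passed (exact binomial test, adjusted p = 0.0148), and 1.06, above expectation, against the share of protein-coding genes (exact binomial test, adjusted p = 0.744). Chromosomes I, II and IV had 73, 58 and 71 peaks, with adjusted exact binomial p values from 0.293 to 0.798.

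**Figure D5:**
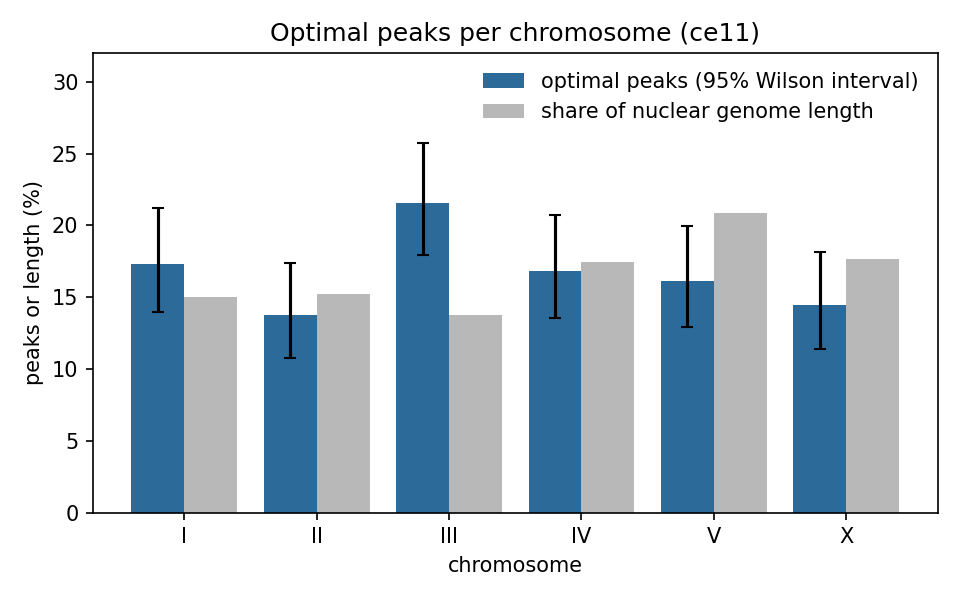
Percentage of the 422 optimal peaks on each chromosome (blue, with 95% Wilson intervals) and that chromosome's percentage of the nuclear genome length (grey). Chromosome III stands at 21.6% against 13.7%, and chromosome X at 14.5% against 17.7%.

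The strain carries a dpff-1 transgene and an unc-119 mutation. The plan took the transgene to carry an unc-119 marker, so both loci were examined for an effect of added copies. Peaks were called against a control. If that control came from the same strain, added copies could raise both alike and leave no peak. No optimal summit lay within 20 kb of dpff-1 (WBGene00016200; chromosome III, 5903563 to 5906346, minus strand) or of unc-119 (WBGene00006843; chromosome III, 10902641 to 10908935, plus strand), where shifts gave means of 0.294 and 0.330 (one-sided permutation p = 1 for each). Without replicate 3, 1 summit lay near dpff-1, 0.746 above the mean of the shifts (permutation p = 0.192). With so low an expectation, the test could show an excess but no depletion. The region of highest signal within 20 kb ranked 1117 in the pooled list for dpff-1 (signal 69.2) and 4180 for unc-119 (signal 50.4). The density of pooled regions was 3.97 and 2.81 per 10 kb around the genes, against 2.99 over the genome.

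Sequence at the summits was richer in G and C than nearby sequence. Sequence within 50 bp of a summit had a mean GC content of 43.5%, against 37.1% for the flanks 450 to 550 bp away, a mean difference of 6.34 percentage points (SD 10.7, n = 422 peaks, higher at 292 of them; two-sided sign-flip permutation test, p = 1e-05, the smallest the resamples can give). Of 2080 canonical 6-mers, 47 differed in presence between summit and right flank (exact McNemar test, Benjamini-Hochberg adjusted p under the threshold of 0.05), 25 higher at summits and 22 higher in the flank; 263 had an unadjusted p under 0.05. The count depended on the replicate used and on the peak set: without replicate 4, 12 words passed, 4 of them higher at summits and 7 of them among the 47, and with the 211 peaks of higher signal 15 passed, 7 of them higher at summits. Of the 25 higher at summits, 20 hold the dinucleotide CG, such as GCGCGC (30 peaks at the summit, 3 in the flank), CGCACA (38 and 8) and CGCGCA (37 and 7), and 5 do not, such as AAACAC (46 and 19) and AGTGTC (20 and 4). The word with the smallest exact p was AAAAAT, lower at summits (118 and 201). Without the summits near tRNA, snRNA and snoRNA genes, a setting chosen after seeing the data, 10 words passed and 3 of them were higher at summits. With the left flank, 29 words passed, of which 18 were among the 47. Without replicate 3, 39 passed, of which 22 were among the 47.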

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

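The tests of regions below the optimal set were chosen after the enrichment within it was seen. The pooled list continues below the optimal set. The 408 regions ranked 423 to 844 that overlapped no optimal peak (signals 74.2 to 88.97) also lay near short RNA genes. Summits within 250 bp of a tRNA gene numbered 37, against a mean of 1.25 and a highest count of 5 under circular shifts, and 17 lay near a snoRNA gene, against a mean of 0.895 and a highest count of 5 (two-sided permutation tests, adjusted p = 0.00599 for each, from the smallest p the shifts can give). For snRNA genes there were 2, against 0.329 (adjusted permutation p = 0.126). The signal at tRNA and snoRNA genes therefore did not end where the IDR threshold ended the set. With 2 samples, no test for a deviating sample was possible.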

How the results depend on the processing

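Leaving out summits near tRNA, snRNA and snoRNA genes was chosen after seeing the data, as were the alternatives for chromosome III, the word on X and the ranks of named peaks. Over the 14 results that answer a comparison, 71 of 83 alternative values kept direction and side of the threshold or stayed within their spread, 6 moved, 1 passed the threshold and 5 turned direction without passing it. The top pooled peaks without IDR are the optimal set itself and count among the 71 without testing anything. With summits required within 100 bp, replicate 3 recovered 58.5% of the optimal set. With a window of 250 bp, 0 gene lists passed, and the odds ratio of ribosomal proteins was 0, because their summits lie farther upstream. The X share was 0.711 times its expectation without replicate 3 (exact binomial test, adjusted p = 0.0148) and 0.831 without replicate 4, but 1.06 against the share of protein-coding genes (exact binomial test, adjusted p = 0.744). Summits near dpff-1, fewer than under shifts as reported, exceeded the mean of the shifts by 0.416 within 40 kb and by 2.03 in the top 5000 pooled regions, and differed from it by -0.287 to 0.746 when either replicate was left out. The difference in signal at promoters was 0.003564 with the 211 peaks of higher signal. The number of 6-mers, 47 as reported, was 15 with the 211 peaks of higher signal, 29 with the left flank, 10 without summits near tRNA, snRNA and snoRNA genes, and 12 to 39 when either replicate was left out (4 to 21 higher at summits, against 25). Chaperones passed with those 211 peaks (exact test, adjusted p = 0.0165) and with 1000 bp (exact test, adjusted p = 0.000979), and miRNA genes missed the threshold without replicate 3 (permutation test, adjusted p = 0.0617). Of 247 alternative values of 69 other results, 221 were the same in this sense, 20 moved, 3 weakened, 2 strengthened and 1 reversed. Where the construction does not show it, the cause was not tested.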

Other observations

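Families of short RNA genes were counted separately. Of the 18 sls-2 genes, 9 had a summit within 250 bp (50%, Wilson 95% interval 29.03 to 70.97), while 0 of 12 sls-1 genes, which encode the leader given to most trans-spliced mRNAs, had one (upper limit 24.2%). None of the 12 smy genes had one. Repeated sequence was counted only around called summits, so whether reads could be placed at the sls-1 genes was not checked. A lack of summits there may therefore not be a lack of signal. The difference between these families was not tested, and the family counts were made after seeing the data. Among the other snRNA genes, 11 of 89 had a summit (12.4%), against 37 of 346 snoRNA genes (10.7%) and 38 of 612 tRNA genes (6.21%). The tRNA genes were spread over many amino acids, with alanine highest (6 of 34) and 0 of 27 for aspartate. The RNA components of ribonuclease P (rpr-1, rank 5) and of ribonuclease MRP (mrpr-1, rank 50, signal 155.1) each held a summit.

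The tests of strongly transcribed lists, of X against autosomal matches of the word, of chromosome III in ranges of rank and of the transgene loci as a source of the chromosome III excess were chosen only after the results were seen, and all 3 patterns were found and tested on the same data. The design has a single group, so no biological group explanation was tested.

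The first pattern is the 88 summits at tRNA, snRNA and snoRNA genes. GC content argues little for it, since positions matched on chromosome and GC content gave a mean of 3.97 with a central 95% of 1 to 9. Reads shared between repeated copies also argue little for it close to the summit, since most 36-mers within 50 bp were repeated at 7.95% of these summits (7 of 88, Wilson 95% interval 3.91 to 15.5). Of the 7, 6 were among the 33 tRNA summits, 1 among the 20 snRNA summits and 0 among the 36 snoRNA summits. Of the 334 other summits, 5 were mostly repeated, so repeats were commoner at tRNA summits, though a minority there. Gene bodies farther from the summit, such as sls-2.2 at 169 bp, were not covered by this count. How the authors handled reads that match several places is not known here. What stays open is that signal may arise at any strongly transcribed gene: 6 such lists together had an odds ratio of 4.79 for a peak (95% interval 2.31 to 8.95, 11 of 331 genes; two-sided Fisher's exact test, p = 4.5e-05), but 6 of the 11 genes were ribosomal proteins and 3 chaperones, whose counts had been seen, and core histones (0 of 72) and the proteasome (0 of 33) had none. The odds ratio intervals of core histones and of the proteasome reached 6.96 and 15.7, so their lack of a peak decides nothing. Without the ribosomal proteins the odds ratio of the joined lists was 2.74 (95% interval 0.868 to 6.62, Fisher's exact test, p = 0.0416). The p is under 0.05 while the interval includes 1, so the 2 measures disagree. The condition first written, an interval above 1 for the 6 lists, was met. An interval above 1 without the ribosomal proteins was required only after the values had been seen. With no untagged strain analysed here, strong transcription and DPFF-1 binding cannot be told apart.

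The second pattern is on X, where 10 of 61 summits (16.4%, Wilson 95% interval 9.16 to 27.6) and 0 of 361 autosomal summits lay within 100 bp of a match, with up to 1 mismatch, to TCGCGCAGGGAG, a word known from X recruitment sites of the dosage compensation condensin complex; among them were those in an intron of mom-1 (rank 6), near C18A11.t2 (rank 19) and in pks-1 (rank 63). Base composition of the word does not give this, since 1000 shuffled words matched at most 3 X summits, and repeated copies do not, with 0% of the 10 summits mostly repeated (upper limit 27.8%). With no mismatch allowed, X held 3 matches, of which 1 had a summit, so the pattern rests mostly on matches with 1 mismatch. Of 32 matches on X with up to 1 mismatch, 13 had a summit, against 0 of 37 on autosomes (lower 95% limit of the odds ratio 5.08), but this restates that no autosomal summit had the word and tests nothing further. Whether DPFF-1 signal marks recruitment sites, or any open or highly occupied site, therefore stays open. The rank 19 peak, with 2 matches of the word within 100 bp, is also among the summits near tRNA genes and so counts in both patterns. In the regions ranked 423 to 844, 0 of 55 on X had the word.

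The third pattern is the excess of peaks on chromosome III, which remained past the threshold with peaks within 5 kb counted once (exact binomial test, adjusted p = 0.00107) and against the share of protein-coding genes (exact binomial test, adjusted p = 1.5e-05), so neither neighbouring peaks nor gene number accounts for it. Extra copies of the transgene loci do not either, with 0 summits within 20 kb of dpff-1 or unc-119. Greater coverage of chromosome III than in the control may account for part of it or more: the ratio to expectation, 1.57 in the optimal set, was 1.23 (95% interval 1.20 to 1.26) among all pooled regions outside it, under the bound of 1.28 that had been set in advance to exclude this explanation. That set is mostly weak regions, however, and the ratio was 1.35 (1.13 to 1.59) for those down to rank 1000, 1.39 (1.22 to 1.58) for the next 1000 and 1.32 (1.23 to 1.43) from there to rank 5000. Lower regions may also be binding sites, so the explanation is left open.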
